A study of Drosophila melanogaster with 36 samples.

How the data were processed

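RNA from pools of 40 body parts of wild-type Dahomey males was sequenced on the Illumina HiSeq with 50 cycles in single reads, non-directional libraries and 4 samples per lane. The males had been raised at 100 larvae per vial, stored 10 per vial after eclosion and kept singly for 5 days from the age of 1 day. They were then left alone or given rival wild-type males for 2, 26 or 50 h, frozen, and separated into abdomen and head with thorax. The 2 treatments, 3 times and 2 body parts make 12 groups of 3 replicates, or 36 libraries.

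The authors' deposited tables, 1 per library, hold read counts per gene as whole numbers, not scaled to a common total, under FlyBase gene identifiers. The aligner, the counting program, the genome build and the annotation release are not given in the sources used here. Genes without a read are left out of a table and were set to 0. The tables name 15513 genes, and 12020 of them appear in every library. Symbols and positions come from the Ensembl 115 annotation of the BDGP6 genome, which matched 14839 identifiers (95.7%). The other 674 keep their identifier and have no position.

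The values themselves show how reads were counted. Where 1 annotated gene lies inside another on the same strand, the host gene held at least the count of the nested gene in 418 of 424 pairs (98.6%, 95% Wilson interval 97.0 to 99.4%). On the opposite strand this was so in 901 of 931 pairs (96.8%, 95.4 to 97.7%), against 958 of 1355 random pairs (70.7%). Reads were therefore counted over the whole gene and for every gene they overlap, and the fold changes of nested or overlapping genes cannot be separated. In addition, 16 genes, among them rut and Snap25, had counts within 1.19-fold of each other in every library. Together they took 5.98 to 14.4% of the library totals, so their fold changes cannot be separated either. The cause was not tested. Genes that may share reads (5403, or 34.8%) were marked, by overlap or by counts matching those of another gene (454 genes). Each count was also made without the marked genes. No pair of libraries in a group looked duplicated, since chi-square over its degrees of freedom was at least 47.3 in the 36 pairs.

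Library totals ran from 33090403 to 110566393 counts. A floor of 3 counts corresponds to 0.027 to 0.091 CPM (counts scaled to the library total), and covers counting error only. The Wilson intervals treat the nested pairs as independent and do not measure the spread between libraries. Each replicate is a pool, and the labels state only that the 3 replicates are biological. If pools shared parents or vials, the p-values would be too small.

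Differences were tested with edgeR 4.0.16 (R 4.3.3) on the raw counts, with TMM scaling, the filterByExpr filter, 1 coefficient per group and the quasi-likelihood F test. Benjamini-Hochberg adjusted p under 0.05 counted as past the threshold. The 18 libraries of 1 body part shared a fit with 13828 genes in the abdomen and 12756 in head and thorax. The questions between body parts used all 36 libraries and 14079 genes. The labels do not state whether the body parts of the same group and number came from the same males. That fit did not pair them. In each body part, rivals were compared with no rivals at 2, 26 and 50 h and as the mean over the 3 times. The interaction of rivals with time, the change from 2 to 50 h without rivals, the interaction of rivals with body part and the difference between body parts were also tested. Mean CPM values are TMM-scaled, with the SD over replicates, as are the points in the plot of CG3739 and CG9436 by time. Other CPM values of single libraries are counts over the library total without TMM scaling. They are therefore not on the same scale as the means.

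In the abdomen the replicate number paired the libraries. The residual correlations of same-number libraries were 0.358, 0.385 and 0.656 at 2 h, 0.359, 0.585 and 0.53 at 26 h, and 0.198, 0.633 and 0.562 at 50 h, and 18 of 18 libraries lay closest to their own number. For the abdominal comparisons of rivals, a fit with replicate number as a block therefore stands beside the fit without it. In the other comparisons not every pair had a correlation over 0.1, so their blocked values are given mainly with the alternatives.

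The lists of genes were fixed before the data were examined, as were the comparisons, the tests, the rule for naming genes and most of the alternatives. There were 28 lists: seminal fluid, ejaculatory duct and bulb, testis, antimicrobial peptides, immune recognition, Turandot stress factors, heat shock, odorant receptors, gustatory receptors, ionotropic receptors, odorant binding proteins, pheromone and courtship genes, aggression neuromodulators, learning and memory, clock, phototransduction, flight muscle, glutathione transferases with cytochromes P450, Jonah and trypsin proteases, sugar digestion, insulin and nutrient signalling, female reproductive genes, hemocytes, fat body, Malpighian tubule, mitochondrially encoded transcripts, ribosomal proteins and oxidative phosphorylation. Another list, of ribosome assembly genes, was written after the called genes had been seen. Lists of at least 5 members were tested with camera (limma 3.58.1) with a preset correlation of 0.01 between genes. Camera with an estimated correlation and fry, which tests whether a list moves on balance 1 way without comparing it with other genes, stand beside it. Members past the threshold were counted over all genes tested and adjusted over the list alone.

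Genes were named by rule. At each time, up to 12 genes were taken in each direction with the largest fold change among those past the threshold, with log2 CPM of at least 1 and no overlap between the groups. Chance alone keeps 3 and 3 libraries apart in 10% of genes. Without overlap, 3 of 3 same-number pairs agree by definition, so that count adds nothing for genes named in this way. Where fewer than 5 qualified, the 5 with the smallest p were added as not past the threshold. The mean over times required 1 sign at all 3 times, the change with time took 6 genes in each direction, the body parts took 12 with log2 CPM of at least 5, and each interaction took the 6 smallest p. Up to 4 members represent a list, and 12 genes of mating and behaviour were always looked up.

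Alternatives were upper quartile and DESeq2 (RLE) scaling, no filter, a mean of at least 5 CPM, limma-voom, DESeq2 1.42.0, the replicate block, exclusion of genes that share reads, leaving out each library or replicate number, and the groups compared alone. Other splits of the samples were all run or, where there were more than 100, 100 were drawn. Correlations across libraries used 1e+05 permutations. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

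The fit was tested on simulated data with known changes in genes with log2 CPM of at least 1, each gene drawn independently. The percentages therefore do not cover weaker genes or genes that vary together between pools. At 26 h in the abdomen it found 49.2% of changes of 0.5 on the log2 scale, 91.7% of those of 1 and 93.7% of those of 2. With a simulated replicate effect it found 43.8%, 93.8% and 98.4%, and the blocked fit 71.2%, 98.5% and 98.4%. At 26 h in head and thorax it found 18.4%, 77.8% and 95.1%. Another scaling moved the median of all genes by at most 0.0599 on the log2 scale, and no scaling at all by up to 0.113.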

Results

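Transcript levels were measured in pools of male *Drosophila melanogaster* that had been alone or with rival males for 2, 26 or 50 h, separately in the abdomen and in the head with the thorax. Each of the 12 groups held 3 libraries. The 18 abdomen libraries had totals of 35443602 to 92497607 counts, and the 18 libraries of head and thorax had 33090403 to 110566393. Transcripts of the mitochondrial genome took 3.43 to 6.59% of the counts in the abdomen and 9.07 to 22.2% in head and thorax. The comparisons ask which genes respond to the presence of rivals, when, and in which part of the body. Values below are mean CPM ± SD with 3 libraries per group unless another number is given, fold changes are rivals over no rivals on the log2 scale with their standard error (SE), and adjusted p-values are Benjamini-Hochberg values from the edgeR quasi-likelihood test.

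After 2 h with rivals, no gene of the abdomen passed the threshold. The C-type lectin gene lectin-28C stood at 23.88 ± 2.49 CPM with rivals and 34.11 ± 1.57 without (log2 -0.52, SE 0.0918, edgeR adjusted p = 0.466, lower in 3 of 3 same-number pairs). CG9436 stood at 44.53 ± 0.846 against 37.04 ± 0.857 CPM, and CG3739 at 178.1 ± 5.08 against 138.5 ± 12.4 CPM, both higher in 3 of 3 pairs. The log2 difference was 0.34 for CG12057 and -0.74 for CG33511, and the adjusted p of all 5 genes was at least 0.466. The Jonah and trypsin proteases, digestive enzymes of the gut, were higher in 24 of 27 members (median log2 0.21, mean -0.01), immune recognition genes in 25 of 29 (median 0.10) and ribosomal proteins in 72 of 81 (median 0.08). Camera with its preset correlation called these 3 lists as well as the fat body (median 0.16), hemocyte (0.19) and ionotropic receptor (-0.19) lists. All 6 calls were lost with an estimated correlation, at adjusted p = 0.462 for the fat body, 0.54 for immune recognition and ionotropic receptors, 0.821 for the proteases, and 0.937 for hemocytes and ribosomal proteins. The fat body median was 0.32 without replicate 2 of no rivals and 0.29 without replicate 3 of rivals.

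edgeR called 0 of 13828 genes at 2 h, 356 had an unadjusted p under 0.05, limma-voom called 0 and DESeq2 2. With the replicate block edgeR also called 0 (1064 with p under 0.05, limma-voom 0, DESeq2 47), and adjusted over the list alone 12 proteases were higher and 1 lower. Without the library of replicate 2 with rivals at 2 h the blocked fit called 69 genes, 63 of them higher. In that library ninaE, the main opsin of the eye, reached 119 CPM, or 1.59% of its level in the matching head and thorax library.

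After 26 h with rivals, transcripts of several seminal fluid proteins, the products of the accessory gland that are transferred to females, were lower in the abdomen. With replicate number as a block, Sfp79B fell by 1.14 on the log2 scale (SE 0.134, edgeR adjusted p = 0.00355), from 9.898 ± 5.23 to 4.395 ± 1.75 CPM. The gene msopa fell by 0.61 (SE 0.071, edgeR adjusted p = 0.00355), from 159.9 ± 25.1 to 104.4 ± 11.5 CPM. Acp76A, a serpin of the accessory gland (FBgn0015586, 3L:19050757 to 19052026), fell by 0.51 (SE 0.0632, edgeR adjusted p = 0.00355), from 171.9 ± 11.1 to 121.1 ± 13.5 CPM. Sfp70A4 fell by 0.48, from 82.98 ± 14.1 to 59.54 ± 11.0 CPM, and CG10433 by 0.30, from 276.2 ± 20.2 to 224.3 ± 15.9 CPM. Each was lower in 3 of 3 pairs, as the naming rule requires.

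Of the 58 seminal fluid genes tested at 26 h, 52 were lower with rivals (median log2 -0.17). In the blocked fit 5 members passed over all genes, and 32, all lower, adjusted over the list alone. Without the block 0 members passed over all genes and 2 adjusted over the list alone. Camera called the list (9.54e-16 without the block) but with an estimated correlation the adjusted p was 0.737, and 0.185 with the block, while fry gave 0.0263 in the blocked fit. The ejaculatory duct and bulb list was lower in 13 of 15 members (median -0.13), with 4 members past the threshold adjusted over the list alone in the blocked fit. Its adjusted p was 0.865 with an estimated correlation, 0.266 with the block, and 0.0349 by fry in the blocked fit. Without replicates 1 and 3 of no rivals the medians of the unblocked fit were -0.25 and -0.09 for the seminal fluid list and -0.22 and -0.01 for the duct and bulb list. Among the always-named seminal fluid genes, the sex peptide gene SP had a log2 difference of -0.16 (94.87 against 106.1 CPM), Acp26Aa -0.29 (301.5 against 368.7), Acp62F -0.22 and Acp36DE -0.14, none of them past the threshold.

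Among the other genes called at 26 h in the blocked fit, the ubiquitin protease gene Usp16-45 rose by 0.29 (77.73 ± 3.53 against 63.68 ± 6.9 CPM, edgeR adjusted p = 0.0119). The overlapping genes kappaB-Ras and CG30503, which share their reads, had 1 common rise of 0.37 (42.83 ± 2.7 against 33.19 ± 2.71 CPM). CG32032 fell by 0.64, CG31106 by 0.43 and the unnamed gene FBgn0261056 by 0.65. Each of these 6 genes moved the same way in 3 of 3 pairs, as the naming rule requires. Called as well, but outside the naming rule and listed after their values were seen, were CG8837, GstZ2, Ugt37A3 and edin, which stood at 75.1 CPM in replicate 3 without rivals and at 0.105 CPM or less in the other 5 libraries. Without the block, Acp76A, CG31106, wcd, CG32024 and FBgn0039236 had the smallest p (adjusted 0.354 to 0.622). Antimicrobial peptides were lower in 25 of 27 members (median -1.66, adjusted p = 0.737 with an estimated correlation). Members of the Turandot stress factors were lower in 5 of 5 (median -1.35), immune recognition in 21 of 29 and the Jonah and trypsin proteases in 16 of 27, while oxidative phosphorylation genes were higher in 66 of 86 (median 0.06), each with adjusted p = 0.865 with an estimated correlation. The Turandot median was -0.67 without replicate 1 of no rivals and -2.67 without replicate 2 of rivals, and that of oxidative phosphorylation ran from 0.00 (without replicate 2 of rivals) to 0.12 (without replicate 1 of rivals). In replicate 3 without rivals at 26 h the antimicrobial transcripts stood 7.22-fold above the next library of the group, and without it the median of their list was -0.18.

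edgeR called 0 of 13828 genes at 26 h without the block (710 with p under 0.05, limma-voom 0, DESeq2 2) and 15 with it, 4 higher and 11 lower. Leaving out 1 of the 6 libraries gave 6 to 11 blocked calls, and CG31106 and FBgn0261056 were called in none of these 6 fits. The count was 9 without replicate 1, 7 without replicate 2 and 6 without replicate 3 of no rivals, and 11, 7 and 8 without replicates 1, 2 and 3 of rivals. The fry call of the seminal fluid list was lost without replicate 2 (0.163) or 3 (0.150) of no rivals or replicate 2 (0.102) or 3 (0.172) of rivals, and that of the duct and bulb list without the same libraries (0.20, 0.206, 0.102 and 0.172).

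After 50 h with rivals the largest called rise in the blocked fit was that of the unnamed gene FBgn0025687 (log2 0.95, SE 0.124, edgeR adjusted p = 0.00617), from 16.11 ± 1.11 to 31.78 ± 10.3 CPM. CG3739 rose from 151.7 ± 13.4 to 224.6 ± 22.8 CPM (log2 0.57, edgeR adjusted p = 0.00875), CG31288 from 62.15 ± 2.73 to 88.2 ± 9.19 CPM (0.50) and CG13659 from 76.0 ± 1.9 to 104.3 ± 9.56 CPM (0.45). Genes of ribosome assembly were among those that rose: RIOK1, a kinase of small-subunit maturation (0.49, 5.097 ± 0.368 against 3.63 ± 0.445 CPM), CG4554, the counterpart of yeast Utp20 (0.45, 12.4 ± 1.44 against 9.122 ± 1.89 CPM), and CG8545 (0.38), which shares reads with dgt5 (0.34). The pyrimidine breakdown gene su(r) rose by 0.48 (51.58 ± 9.84 against 36.87 ± 3.41 CPM), CG1213 by 0.47, FBgn0034496 by 0.46 and CG3808, which shares reads with CG18135, by 0.41. CG14893 fell by 0.61 (14.57 ± 1.45 to 9.553 ± 0.51 CPM, edgeR adjusted p = 0.00863), CG11911, which shares reads with Plc21C, by 0.51, the NPC2-family gene Npc2d by 0.42, and salt, which shares reads with CG1910, by 0.41. Each of these genes moved the same way in 3 of 3 pairs, as the naming rule requires.

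The seminal fluid list was lower at 50 h in 55 of 58 members (median -0.12), with 12 members past the threshold adjusted over the list alone in the blocked fit and 0 without it. Its adjusted p was 0.725 with an estimated correlation, and in the blocked fit 0.321 with an estimated correlation and 0.0666 by fry. The ejaculatory duct and bulb list was lower in 14 of 15 members (median -0.13, adjusted p = 0.725 with an estimated correlation, 0.13 with the block). Adjusted over the list alone 3 of its members passed in the blocked fit, and fry gave 0.0169. In the unblocked fit the seminal fluid median was -0.21 and -0.06 without replicates 2 and 3 of no rivals and -0.07 and -0.26 without replicates 1 and 3 of rivals, and that of the duct and bulb list was -0.19, -0.06, -0.08 and -0.20 without the same libraries. The testis list was lower in 40 of 45 members (median -0.07, or -0.04 without replicate 2 of no rivals, adjusted p = 0.725 with an estimated correlation). Immune recognition genes were higher in 26 of 29 members (0.725), sugar digestion genes in 15 of 20 (0.758), and oxidative phosphorylation genes in 61 of 86, ribosomal proteins in 69 of 81 (both 0.78), where the values in brackets are adjusted p with an estimated correlation. The Jonah and trypsin proteases had a median of -0.06 and a camera call toward lower levels but a mean of 0.00437 (adjusted p = 0.78 with an estimated correlation).

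edgeR called 0 of 13828 genes at 50 h without the block (556 with p under 0.05, limma-voom 0, DESeq2 11, smallest adjusted p = 0.094) and 17 with it, 13 higher and 4 lower. The blocked calls fell to 0 without replicate 2 or without replicate 3 of no rivals, to 6 without replicate 1 of no rivals, and to 5 and 7 without replicates 1 and 2 of rivals, and numbered 20 without replicate 3 of rivals. Without the block, leaving out replicate 3 of rivals gave 1 call. The fry call of the duct and bulb list was lost without any library of no rivals (0.102, 0.0528 and 0.0715 for replicates 1, 2 and 3) and without replicate 1 (0.113) or 2 (0.083) of rivals.

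A list of ribosome assembly genes was written after the called genes had been seen, so its result is not independent of them. Of its 58 tested members, 53 were higher with rivals at 26 h (median 0.16, unadjusted p = 0.0013 by camera with an estimated correlation) and 53 at 50 h (median 0.21, 7.06e-05), against a median of -0.02 at 2 h (0.561). The 49 members that had not prompted the list gave medians of 0.14 (0.00376) and 0.18 (0.000169). With the block, 3 members passed over all genes at 50 h and 36 adjusted over the list alone. In head and thorax the medians were -0.06 at 26 h (0.261) and 0.07 at 50 h (0.551).

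**Figure D1:**
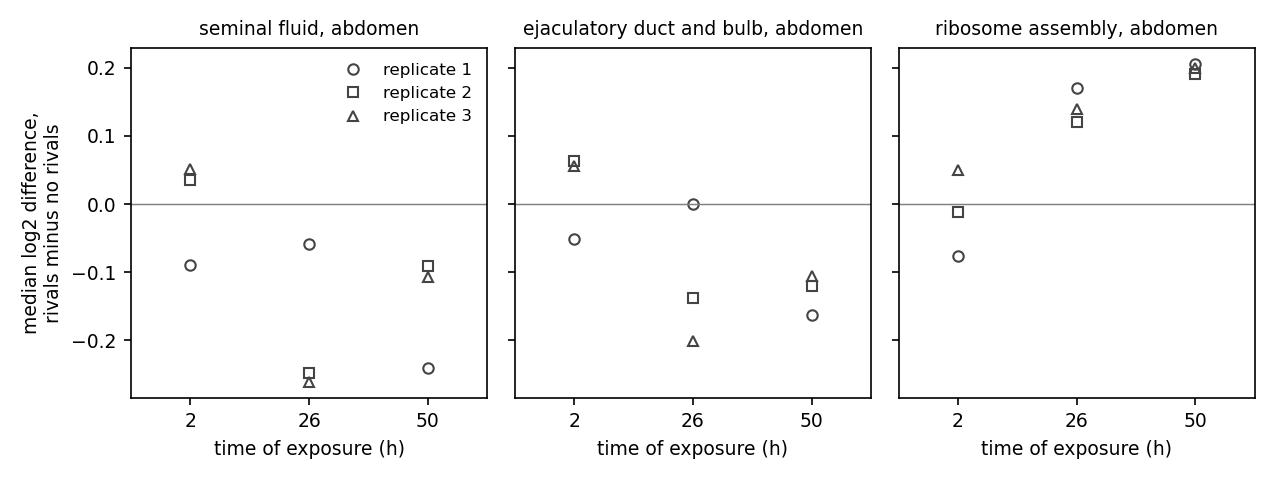
Median log2 difference between rivals and no rivals over the members of 3 lists in the abdomen, with each point a pair of libraries with the same replicate number and the time of exposure (h) on the x axis. Seminal fluid medians at 26 h were -0.06, -0.25 and -0.26, those of the ribosome assembly list at 50 h were 0.21, 0.19 and 0.20, and 7 of 9 pairs lay below 0 for the seminal fluid and the duct and bulb lists.

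Over the 3 times together, 2 genes of the abdomen rose with rivals without the block. CG3739 (FBgn0038702, 3R:19393360 to 19395188) stood at 195.1 ± 25.1 CPM with rivals and 147.1 ± 12.3 without (9 libraries per side, log2 0.40, SE 0.0506, edgeR adjusted p = 0.0141). CG9436 (FBgn0033101, 2R:6757601 to 6758903) stood at 45.07 ± 1.33 against 39.47 ± 2.74 CPM (log2 0.19, SE 0.028, edgeR adjusted p = 0.0355). Both were higher in 9 of 9 same-number pairs. The smallest p below the threshold belonged to wcd, a nucleolar gene of ribosome assembly (0.33), the sugar transporter family gene CG4607 (0.34) and Nepl17, which shares reads with CG33203 (0.55), each with adjusted p = 0.101.

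**Figure D2:**
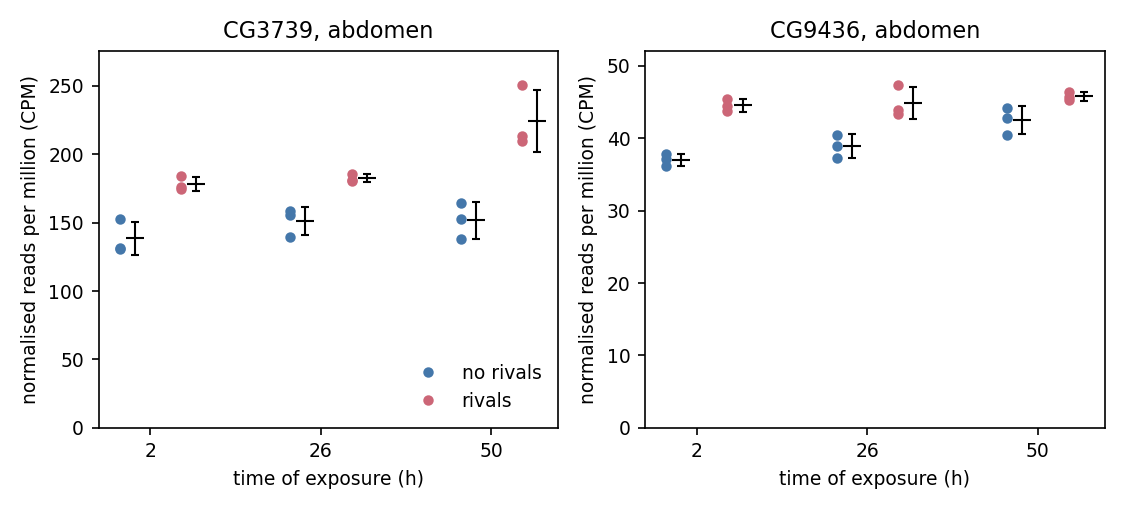
Level of CG3739 and CG9436 in the abdomen (CPM, y axis) by time of exposure (h, x axis), with each point a library and the black marks the mean ± SD of 3 libraries. CG3739 had 224.6 ± 22.8 CPM with rivals at 50 h against 151.7 ± 13.4 without, and all points with rivals lay above all points without at each time for both genes.

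With the block, 52 genes passed over the 3 times, 37 higher and 15 lower. Those that rose included FBgn0025687 (log2 0.51, higher in 8 of 9 pairs), CG4607 (0.34, 9 of 9), wcd (0.33, 8 of 9), su(r) (0.32, 9 of 9), the phosphate transporter family gene CG15096 (0.28, 9 of 9), CG8545 (0.28, 9 of 9), Phyhd1 (0.27, 8 of 9), Ance-5 of the angiotensin-converting enzyme family (0.26, 9 of 9), CG8837 (0.25, 9 of 9), FBgn0040001 (0.24) and dgt5 (0.24). Those that fell included FBgn0085818 (-0.41), CG14893 (-0.40, lower in 8 of 9 pairs), FBgn0261056 (-0.37), Acp76A (-0.27, 8 of 9), CG42782 (-0.27, 8 of 9), CG43145 (-0.26, 9 of 9), FBgn0039236 (-0.25), CG31230, which shares reads with CG7702 (-0.20), CG42240 (-0.17, 7 of 9), CG30177 (-0.17) and the seminal fluid protease gene Sems (-0.14, 9 of 9). edgeR adjusted p-values of these genes ran from 0.00432 for CG3739 and CG14893 to 0.0414 for Ance-5.

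The seminal fluid list was lower in 53 of 58 members over the 3 times (median -0.11). In the blocked fit 4 members (msopa, Acp76A, Sems and Sfp79B) passed over all genes and 31 adjusted over the list alone, all lower. The camera call (1.16e-13) was lost with an estimated correlation (adjusted p = 0.744, and 0.155 with the block), and fry gave 0.0159 in the blocked fit. The duct and bulb list was lower in 14 of 15 members (median -0.09, 6 past the threshold adjusted over the list alone in the blocked fit, fry 0.0159), and its adjusted p with an estimated correlation was likewise 0.744, or 0.155 with the block. Oxidative phosphorylation genes (63 of 86 higher, 11 adjusted over the list alone with the block), ribosomal proteins (68 of 81 higher), sugar digestion (17 of 20 higher), testis (37 of 45 lower), antimicrobial peptides (21 of 27 lower, median -0.31, or -0.04 without replicate number 3), ionotropic receptors (25 of 36 lower) and mitochondrially encoded transcripts (21 of 24 lower, median -0.17) were called by camera. These 7 calls were lost at adjusted p = 0.744 with an estimated correlation.

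edgeR called 2 of 13828 genes without the block (934 with p under 0.05, limma-voom 1, DESeq2 22). Without any 1 replicate number the unblocked count was 0, and the blocked count was 2, 10 and 1 without replicate numbers 1, 2 and 3. Without the library of replicate 2 with rivals at 2 h, in which ninaE stood at 119 CPM, the unblocked count was 1 (CG3739) and the blocked count 236, 142 higher and 94 lower. Over the alternatives the adjusted p of CG3739 ran from 7.47e-10 to 0.885 and that of CG9436 from 9.92e-06 to 0.964, the highest without 1 replicate number. The seminal fluid fry call was lost without replicate number 2 (0.246) or 3 (0.355).

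Whether the response in the abdomen differed between times was tested as an interaction. Without the block, edgeR called 0 of 13828 genes (412 with p under 0.05, limma-voom 0, DESeq2 15). CG33511, CG32024, CG3808, CG33510 (adjusted p = 0.443), the ubiquinone synthesis gene Coq2 (0.51) and lectin-28C (0.765) had the smallest p. With the block, edgeR called 1 gene, CG11911 (FBgn0031249, 2L:320279 to 321248, edgeR adjusted p = 0.00529), which shares reads with Plc21C. It stood at 64.7 ± 7.91 CPM with rivals at 50 h against 92.55 ± 17.6 without. Next were msopa (0.0555), CG7720 (0.0559), CG10433 (0.0696), the gluconeogenesis gene Pepck1 and CG4554 (both 0.0756). The blocked count was 111, 19 and 0 without replicate numbers 1, 2 and 3 (0.351 for CG11911 without number 3), and 73 without replicate 2 with rivals at 2 h.

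The fold changes of the 13828 genes at 26 and 50 h had a Pearson r of 0.123 across genes (0.217 with the block), and those at 2 and 26 h of -0.129. Genes are not independent replicates. No gene was called at both 26 and 50 h with the block (expected 0.00376 higher and 0.00318 lower, Fisher's exact p = 1 for each).

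In males without rivals, the abdomen at 50 h was compared with that at 2 h, the same hour of the day. CG7214 stood at 0.8559 ± 0.149 CPM at 50 h and 3.353 ± 0.709 at 2 h (log2 -1.97), and Oatp26F, which shares reads with CG34345, at 2.759 ± 0.714 against 1.341 ± 0.0535 (1.04, both adjusted p = 0.111 by edgeR). The calcium-binding protein genes Scp1 (-0.83, 29.22 ± 4.71 against 51.96 ± 8.07 CPM) and TpnC41C, a muscle troponin C (-1.01, 9.57 ± 1.46 against 19.3 ± 3.8 CPM), and the proteasome gene Prosalpha3T (-0.28) had adjusted p = 0.129. All were shifted the same way in 3 of 3 pairs. Seminal fluid genes were lower in 49 of 58 members (median -0.17, 2 higher and 8 lower adjusted over the list alone), ribosomal proteins higher in 76 of 81 (0.16) and Jonah and trypsin proteases in 24 of 27 (0.25), at adjusted p = 0.551 with an estimated correlation. Flight muscle genes were lower in 21 of 24 (-0.10, 3 adjusted over the list alone), antimicrobial peptides in 26 of 27 (-1.03) and testis genes in 37 of 45, at 0.411 with an estimated correlation. The seminal fluid median was -0.10 and -0.32 without replicates 2 and 3 at 50 h, the antimicrobial median -0.40 without replicate 3 at 2 h, and the flight muscle median -0.03 and -0.24 without replicates 1 and 2 at 2 h and -0.21 without replicate 1 at 50 h.

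Camera also called the insulin (12 of 19 higher, median 0.11, 1 higher adjusted over the list alone), clock (12 of 14, 0.13), Malpighian tubule (12 of 15, 0.06) and Turandot (5 of 5 lower, -1.92) lists. Their adjusted p with an estimated correlation was 0.0753, 0.101, 0.288 and 0.551, and the Turandot median was -0.72 without replicate 2 at 2 h. edgeR called 0 of 13828 genes (1029 with p under 0.05, limma-voom 0, DESeq2 47). With the replicate block it called 195, 131 higher and 64 lower, so the count depends on the block. Same-number libraries were not alike throughout in this comparison (lowest residual correlation -0.0107).

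In head and thorax, no gene passed the threshold for rivals at 2 h. Seminal fluid genes were lower with rivals in 46 of 47 members (median log2 -3.71), 39 of them adjusted over the list alone, and testis genes in 42 of 43 (-2.27), 23 adjusted over the list alone. Both lists had adjusted p = 0.448 with an estimated correlation. The sex peptide gene SP stood at 0.08868 CPM with rivals against 2.381 without, and Acp36DE at 2.226 against 47.8. In the single library of replicate 1 without rivals, Acp36DE reached 128 CPM and SP 6.48, and the seminal fluid list stood at 4.43% of its level in the abdomen, against 0.0242 to 0.365% in the other 17 libraries of head and thorax. Without that library the medians were -1.18 for seminal fluid and -1.40 for testis genes.

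The smallest p at 2 h in head and thorax belonged to comm3, which shares reads with Phs (-0.41, 13.54 ± 0.484 against 18.03 ± 0.41 CPM), CG3588, which shares reads with kirre (0.43), CG3640, which shares reads with CG4781 (-3.77), scpr-C (-1.86) and Sfp84E (-2.62), each with edgeR adjusted p = 0.421. Camera called 13 further lists, all with adjusted p of at least 0.448 with an estimated correlation. Higher medians were those of hemocytes (0.46), female reproductive genes (0.48), fat body (0.20), insulin signalling (0.14), immune recognition (0.10), ribosomal proteins (0.09), glutathione transferases with cytochromes P450 (0.09) and phototransduction (0.08). Lower medians were those of antimicrobial peptides (-2.84), mitochondrially encoded transcripts (-0.33), sugar digestion (-0.32), pheromone and courtship genes (-0.14) and oxidative phosphorylation (-0.05). Without replicate 3 of no rivals, in which antimicrobial transcripts stood 19.6-fold above the next library of the group, the antimicrobial median was 0.10 and that of oxidative phosphorylation 0.11. The latter was -0.11 and -0.15 without replicates 1 and 2 of no rivals and -0.01 and -0.08 without replicates 1 and 3 of rivals. The fat body median was 0.31 without replicate 1 of no rivals, and the mitochondrial median -0.22 and -0.53 without replicates 2 and 3 of rivals. edgeR called 0 of 12756 genes (1235 with p under 0.05, limma-voom 0, DESeq2 13).

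**Figure D3:**
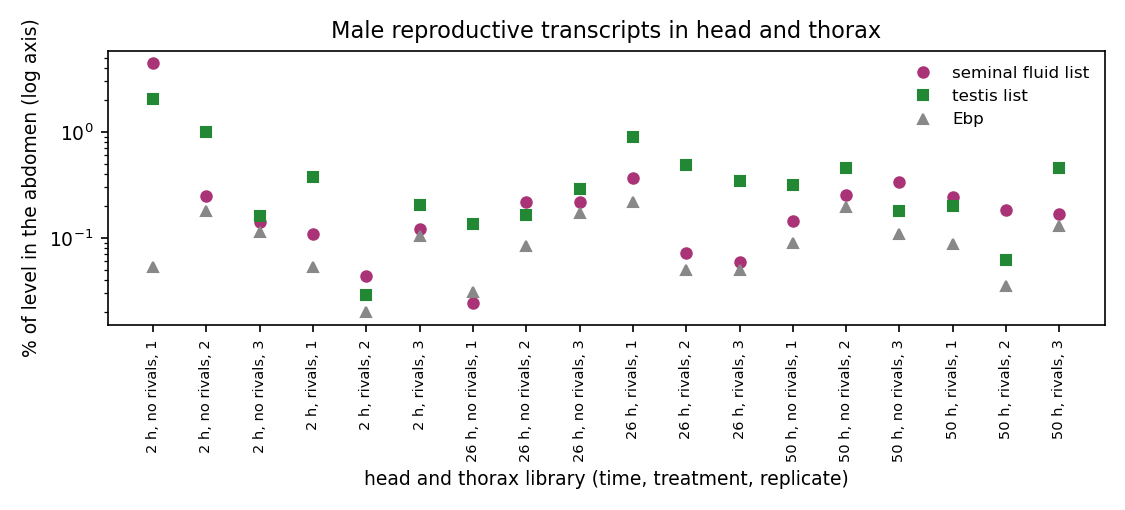
Level of the seminal fluid list, the testis list and Ebp in each library of head and thorax as a percentage of the level in the abdomen (log y axis), with libraries ordered by time, treatment and replicate on the x axis. The library of replicate 1 without rivals at 2 h stood at 4.43% for seminal fluid and 2.05% for testis genes but at 0.0531% for Ebp, a product of the ejaculatory bulb.

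At 26 h in head and thorax, antimicrobial peptides were lower with rivals in 25 of 26 members (median -3.35), 16 of them adjusted over the list alone, and immune recognition genes in 26 of 27 (-0.20), 2 adjusted over the list alone. Both lists had adjusted p = 0.373 with an estimated correlation. In replicate 3 without rivals the antimicrobial transcripts stood 11.9-fold above the next library of its group, and without it their median was -0.50. Testis genes were higher in 42 of 43 (1.40, 0.392) and sugar digestion genes in 17 of 20 (0.47, 1 adjusted over the list alone, 0.373), and oxidative phosphorylation genes in 83 of 86 (0.11, 0.538), with adjusted p with an estimated correlation last in each bracket. In the testis list, replicate 1 with rivals stood at 0.885% of the level in the abdomen, and without it the median was 0.88. The oxidative phosphorylation median was 0.16 and 0.06 without replicates 1 and 3 of rivals.

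Camera also called Jonah and trypsin proteases (0.25), hemocytes (-0.47), odorant binding proteins (-0.18), pheromone and courtship genes (-0.19), learning and memory (-0.09), glutathione transferases with cytochromes P450 (-0.11), heat shock (-0.05), insulin signalling (-0.09) and Turandot factors (-1.29) at 26 h. Their adjusted p was at least 0.373 with an estimated correlation. The Turandot median was -0.84 and -0.78 without replicates 1 and 2 of no rivals and -3.21 without replicate 2 of rivals, and that of heat shock -0.09 without replicate 1 of no rivals and -0.10 without replicate 3 of rivals. CG8785 (-0.48, 7.057 ± 0.966 against 9.822 ± 1.08 CPM), CG31087 (0.88, 3.487 ± 0.667 against 1.899 ± 0.273 CPM), Mrp4, which shares reads with CG6790 (-0.30), CG14500, which shares reads with CG33958 (3.13), and CG8046 (-1.10) had the smallest p (edgeR adjusted p = 0.635). edgeR called 0 of 12756 genes (872 with p under 0.05, limma-voom 0, DESeq2 7).

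At 50 h in head and thorax, heat shock genes were lower with rivals in 14 of 18 members (median -0.40), 10 of them adjusted over the list alone. Hsp70Bc stood at 11.61 ± 1.43 CPM against 17.16 ± 2.7 (log2 -0.56), and Hsp70Bbb (-0.56), Hsp70Bb (-0.54) and Hsp70Ba (-0.51), which encode near-identical chaperones, were alike. Whether the reads of such copies can be told apart was not tested, so they may repeat 1 signal in the counts of members. Camera called the list at 1.05e-17, and the call held with an estimated correlation (adjusted p = 0.0147) and by fry (0.0274). With the replicate block neither called any list at 50 h, the smallest adjusted p being 0.144 with an estimated correlation and 0.0765 by fry. The median deviations of the 3 libraries with rivals were -0.26, -0.36 and -0.23 and those without 0.20, 0.12 and -0.14. With an estimated correlation the call was lost without replicate 1 (0.0523) or 2 (0.0886) of no rivals or replicate 3 of rivals (0.0847), and with the groups compared alone it stood at 0.0453.

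Mitochondrially encoded transcripts were lower at 50 h in 31 of 33 members (median -0.63), with mt:srRNA at -0.87, mt:ND1 at -0.68, mt:Cyt-b at -0.64 and mt:ATPase6 at -0.63. Fat body genes were higher in 13 of 13 members (median 0.38), among them the larval serum protein gene Lsp1beta (0.74), Gnmt (0.63), the lipid transfer gene Apoltp (0.38) and the acetyl-CoA synthetase gene AcCoAS (0.28). Both lists had adjusted p = 0.0386 with an estimated correlation and 0.0913 by fry, with 0 members past the threshold adjusted over the list alone. The mitochondrial call was lost without replicate 1 (0.117), 2 (0.0886) or 3 (0.0774) of no rivals or replicate 2 (0.0762) or 3 (0.265) of rivals, and without replicate 1 of rivals the median was -1.39. The fat body call was lost without replicate 1 (0.117) or 3 (0.130) of no rivals or replicate 1 (0.208) or 2 (0.0762) of rivals, with medians of 0.67 without replicate 2 and 0.18 without replicate 3 of no rivals. With the groups compared alone they stood at 0.246 for the mitochondrial and 0.299 for the fat body list.

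Other lists called by camera at 50 h in head and thorax were odorant receptors (-0.27, adjusted p = 0.0583 with an estimated correlation), hemocytes (0.36, 0.276), sugar digestion (0.28, 0.37), antimicrobial peptides (0.54, 0.552), immune recognition (0.14, 0.564), testis (-0.42, 0.693), aggression neuromodulators (-0.08, 0.693) and seminal fluid (-0.46, 0.813). The seminal fluid median was -0.01 without replicate 3 of no rivals, and the testis median -0.18 and -0.06 without replicate 2 of no rivals and of rivals and -1.06 without replicate 3 of rivals. FBgn0025687 stood at 20.82 ± 6.63 against 12.15 ± 1.65 CPM (log2 0.77), Sclp, which shares reads with lncRNA:CR32660, at 16.97 ± 0.379 against 21.74 ± 0.719 (-0.36) and Nepl3, which shares reads with His3.3A, at 1.215 ± 0.0439 against 2.138 ± 0.421 (-0.82), none past the threshold. edgeR called 0 of 12756 genes (444 with p under 0.05, limma-voom 0, DESeq2 0).

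Over the 3 times in head and thorax, Cln3, the fly counterpart of a human lysosomal disease gene, stood at 39.0 ± 7.02 CPM with rivals and 47.3 ± 8.17 without (9 libraries per side, log2 -0.28, SE 0.0431, edgeR adjusted p = 0.134, lower in 9 of 9 pairs). Sclp (-0.26, 0.451), FBgn0025687 (0.45, 0.819), Obp69a, which shares reads with CG32104 (-0.48, 0.819), and CG15096 (0.48, 0.994) followed. With the replicate block, although the numbers do not pair these libraries throughout, Cln3 had an edgeR adjusted p = 0.0204. Heat shock genes were lower in 14 of 18 members (median -0.17, 5 adjusted over the list alone), mitochondrially encoded transcripts in 30 of 33 (-0.35), and fat body genes higher in 11 of 13 (0.18), each with adjusted p = 0.166 with an estimated correlation. Camera called 12 further lists at 0.173 or above with an estimated correlation. They were seminal fluid (-1.39), antimicrobial peptides (-1.87), testis (-0.37), odorant binding proteins (-0.14), pheromone and courtship (-0.13), learning and memory (-0.08), flight muscle (-0.06), ribosomal proteins (0.07), sugar digestion (0.11), Jonah and trypsin proteases (0.12), hemocytes (0.13) and female reproductive genes (0.24). Without the library of replicate 1 without rivals at 2 h, which held seminal fluid transcripts at 4.43% of the level in the abdomen, the medians were -0.48 for seminal fluid, -0.12 for testis and -0.04 for flight muscle. Without replicate number 3 the antimicrobial median was -0.02 and that of flight muscle -0.02. Without number 1 the median was -0.56 for testis, -0.55 for mitochondrially encoded transcripts and 0.11 for the fat body. Without number 2 the testis median was -0.04, that of flight muscle -0.10 and that of the fat body 0.27, and without number 3 the testis median was -0.68. edgeR called 0 of 12756 genes (473 with p under 0.05, limma-voom 0, DESeq2 6).

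The interaction of rivals with time in head and thorax called 0 of 12756 genes by edgeR (1297 with p under 0.05, limma-voom 0, DESeq2 44). The smallest p belonged to comm3, phu, Nepl6, Acbp5, CG31087 and CG5618, each with adjusted p = 0.463. Fold changes at 2 and 26 h had a Pearson r of -0.421 across genes. The genes of behaviour and courtship that were always looked up did not pass the threshold in either body part at any time. In head and thorax over the 3 times, fru had a log2 difference of -0.04, dsx of -0.11, the tachykinin gene Tk of 0.06, the clock gene per of 0.13 and Or67d, the receptor of a male pheromone, of -0.19. The odorant receptor gene Or47b was not tested. The yolk protein gene Yp1, a marker of females, stood at 1.803 against 1.456 CPM.

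In males without rivals, edgeR called 10 genes that fell and 1 that rose in head and thorax between 2 and 50 h. Myofilin (Mf), a thick filament protein of flight muscle, fell from 4472 ± 370 to 2373 ± 371 CPM (log2 -0.91, SE 0.126, edgeR adjusted p = 0.00729), Act88F, the actin of the indirect flight muscle, from 135 ± 13.3 to 71.03 ± 4.96 CPM (-0.93, SE 0.148, edgeR adjusted p = 0.0244), and flightin (fln) by 0.74 (edgeR adjusted p = 0.00729). The glycolytic gene Gapdh1 fell from 1592 ± 233 to 804.2 ± 110 CPM (-0.99, edgeR adjusted p = 0.0132), Gpdh1 by 0.51 (0.0479) and the ATP synthase subunit gene ATPsyngamma by 0.72 (0.0392). Porin2 fell from 6.891 ± 1.01 to 3.075 ± 0.071 CPM (-1.16, SE 0.134, edgeR adjusted p = 0.00199), SkpB, which shares reads with CG18343, from 17.97 ± 1.74 to 9.172 ± 0.679 CPM (-0.97, edgeR adjusted p = 0.0016), CG13026 from 8.792 ± 1.39 to 3.509 ± 0.332 CPM (-1.32, edgeR adjusted p = 0.00729) and Cln3 by 0.49 (0.0164). Each of the 6 genes with CPM given was lower in 3 of 3 pairs, as the naming rule requires. The ionotropic receptor gene Ir75b rose by 1.03 (0.0479). It, fln, Gpdh1, ATPsyngamma and Cln3 lie outside the naming rule and were chosen after their values were seen.

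Oxidative phosphorylation genes were lower in 83 of 86 members (median -0.42, mean -0.64), 37 of them adjusted over the list alone and 1 over all genes. ATPsynC stood at -0.73, ATPsyndelta at -0.60 and ND-B15 at -0.56. Camera's call (4.52e-42) held with an estimated correlation (adjusted p = 0.0299) and fry gave 0.00522. Flight muscle genes were lower in 22 of 24 members (median -0.42), 14 adjusted over the list alone and 3 over all genes, with Mlc1 at -0.55. The oxidative phosphorylation median was -0.26 without replicate 3 at 2 h. For the flight muscle list the adjusted p was 0.0569 with an estimated correlation and 0.017 by fry. Seminal fluid (-2.65), testis (-1.71), antimicrobial peptides (-2.51), Turandot (-1.75), fat body (-0.24), mitochondrially encoded transcripts (-0.34), sugar digestion (-0.14), phototransduction (0.10), ribosomal proteins (0.08), aggression neuromodulators (0.11, 1 lower adjusted over the list alone) and ionotropic receptors (0.12) were also called by camera, at 0.469 or above with an estimated correlation. The library of replicate 1 at 2 h in this comparison is the one with seminal fluid transcripts at 4.43% of the level in the abdomen, and without it the medians were 0.00 for seminal fluid and -1.03 for testis. Without replicate 3 at 2 h the antimicrobial median was -0.14, and without replicate 2 at 2 h those of Turandot and the fat body were -0.47 and -0.15. The fat body median was -0.48 and 0.04 without replicates 2 and 3 at 50 h, and the mitochondrial median -0.54 without replicate 3 at 50 h.

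edgeR called 11 of 12756 genes, 1 higher and 10 lower (1088 with p under 0.05, limma-voom 11, DESeq2 99). The count was 5 without replicate 1 or replicate 3 at 2 h, 6 without replicate 1 and 2 without replicate 2 at 50 h, and 0 with the groups compared alone. Act88F was not called without any 1 of the 6 libraries, and Gapdh1 not without replicate 1 or 3 at 2 h or replicate 2 or 3 at 50 h. The oxidative phosphorylation call with an estimated correlation was lost without replicate 1 (0.0586) or 2 (0.131) at 50 h or replicate 3 at 2 h (0.401). The fry call of the flight muscle list was lost without replicate 1 (0.0646) or 3 (0.0856) at 2 h or replicate 2 at 50 h (0.0748). With the groups compared alone both lists had 0.425 with an estimated correlation and 0.335 by fry.

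**Figure D4:**
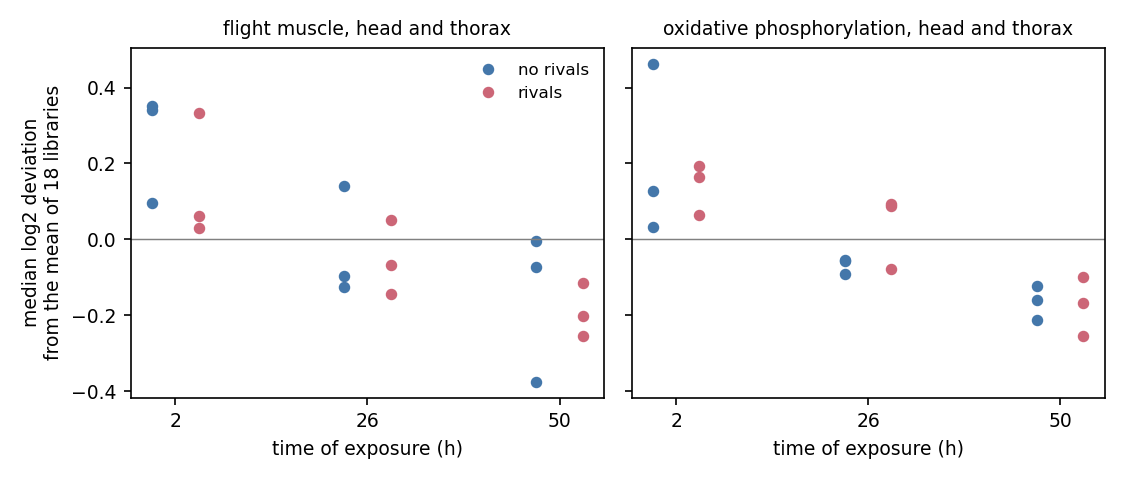
Median log2 deviation of the flight muscle and oxidative phosphorylation lists from the mean of the 18 libraries of head and thorax (y axis) by time of exposure (h, x axis), with each point a library. Without rivals, flight muscle medians were 0.35, 0.10 and 0.34 at 2 h and -0.00, -0.38 and -0.07 at 50 h, and oxidative phosphorylation medians were 0.13, 0.03 and 0.46 at 2 h and -0.16, -0.21 and -0.12 at 50 h.

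Whether the mean response to rivals differed between body parts was tested over all 36 libraries. The long non-coding RNA gene lncRNA:CR43475, which shares reads with loco, had a log2 difference of 2.46 (abdomen minus head and thorax) and CG32986 of 2.20 (both adjusted p = 0.779). Sfp84E (1.35), CR43170 (-0.72), CG6403 (2.60) and the glutathione transferase gene GstD6 (-1.52) followed. Seminal fluid genes had a positive difference in 56 of 58 members (median 1.34, 1 higher adjusted over the list alone) and heat shock genes in 13 of 18 (0.16), both at adjusted p = 0.556 with an estimated correlation. Without the head and thorax library of replicate 1 without rivals at 2 h, in which seminal fluid transcripts stood at 4.43% of the level in the abdomen, the seminal fluid median was 0.35 and the testis median 0.04. Antimicrobial peptides (0.44), testis (0.23), mitochondrially encoded transcripts (0.15), odorant binding proteins (0.06), Jonah and trypsin proteases (-0.11) and sugar digestion (-0.12) were called by camera, with 0.87 for each with an estimated correlation. Without replicate numbers 1, 2 and 3 the testis median was 0.45, -0.01 and 0.54, without numbers 2 and 3 the antimicrobial median was 0.81 and -0.09, and without numbers 1 and 3 the mitochondrial median was 0.30 and 0.02. edgeR called 0 of 14079 genes (405 with p under 0.05, limma-voom 0, DESeq2 0). The mean fold changes of the body parts had a Pearson r of 0.0619 across genes.

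The body parts themselves differed in 12860 of 14079 genes by edgeR, 6874 higher in the abdomen and 5986 lower. Products of the ejaculatory bulb and accessory gland led in the abdomen. EbpII had a log2 difference of 9.85, Ebp of 9.83 (2906 ± 591 against 3.244 ± 2.07 CPM over 18 libraries each), Sfp24Bb of 9.70, Met75Ca and Met75Cb, which share reads, of 9.24, and Dup99B of 9.18, and Sfp87B, Sfp60F, Obp51a, CG43101, Sfp24Ba and CG17242 were also among the first 12. Head and thorax led in CG34324 (-10.19), the mucin gene Muc68D (-10.12), ninaE (-9.78, 11.59 ± 24.1 against 7494 ± 885 CPM), the arrestin gene Arr2 (-9.72), which shares reads with Pex7, and Xport-A (-9.50), a chaperone of rhodopsin, with CG34220, CG3906, CG14645, CG12158, CG14125 and CG43673. Without the abdomen library of replicate 2 with rivals at 2 h, in which ninaE stood at 119 CPM, its abdominal level was 5.968 ± 3.95 CPM over 17 libraries, and the differences were -10.49 for ninaE, -10.38 for Arr2 and -10.13 for Xport-A.

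By list, counting members past the threshold, seminal fluid genes were higher in the abdomen in 57 of 58 members (median 8.57), testis in 44 of 45 (7.93), the ejaculatory duct and bulb in 12 of 15 (6.62) and the Malpighian tubule in 13 of 15 (1.98). Jonah and trypsin proteases were higher in 23 of 27, sugar digestion in 16 of 20, gustatory receptors in 20 of 33 and ionotropic receptors in 20 of 39. Glutathione transferases with cytochromes P450 were higher in 36 and lower in 22 of 76 members, and female reproductive genes higher in 4 and lower in 4 of 9. Phototransduction genes were lower in the abdomen in 27 of 29 (median -5.30), mitochondrially encoded transcripts in 32 of 33 (-2.17), flight muscle in 20 of 24 (-1.69) and oxidative phosphorylation in 67 of 86. Also lower were the aggression neuromodulators in 34 of 41, clock genes in 12 of 14, learning and memory in 20 of 26, pheromone and courtship in 26 of 37, insulin signalling in 13 of 20, odorant receptors in 18 of 30, odorant binding proteins in 28 of 45, heat shock in 12 of 18, hemocytes in 9 of 13, fat body in 9 of 14 and immune recognition in 19 of 29. Antimicrobial peptides were lower in 12 and higher in 3 of 28 members, ribosomal proteins lower in 32 and higher in 7 of 81, and of 6 Turandot factors 0 passed.

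Camera called 16 of these lists between body parts and none with an estimated correlation (smallest adjusted p = 0.0873, for the aggression neuromodulators), while fry called 24. limma-voom called 12875 and DESeq2 13229 genes, and 8469 remained without the genes that share reads.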

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

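The tests of tissue carry-over, of heterogeneity between seminal fluid genes and of their scaling, of the seminal fluid median without the replicate block, and of the ribosome assembly list were chosen only after the result was seen.

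In head and thorax the response of the heat shock list to rivals differed between times, being lower at 50 h than at 2 h (camera on the difference with an estimated correlation, adjusted p = 0.0418, and 0.211 with the replicate block). In the abdomen the response of CG11911 differed between times in the blocked fit (edgeR adjusted p = 0.00529). It was lower with rivals at 50 h in 3 of 3 pairs, which the rule that named it at 50 h requires. It was the 1 gene called, and 15 of 100 splits gave at least as many (highest other 89), so chance is not excluded. The call was lost without replicate number 3 (0.351). CG11911 shares reads itself, so the fit without such genes did not test it. For the ribosome assembly list the difference in response between 26 and 2 h in the abdomen had an unadjusted p = 0.00441 with an estimated correlation, and that between 50 and 2 h 0.000295, but the list was written from genes called for rivals, so these p-values do not test whether its response changes with time. Camera with an estimated correlation gave p = 0.397 and 0.888 for the same differences in head and thorax.

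The first pattern is the lower level of seminal fluid transcripts in the abdomen with rivals, in 52 of 58 members at 26 h and 55 at 50 h. A smaller share of accessory gland tissue as the only cause would lower alike all members made in that tissue alone. In the blocked edgeR fit at 26 h the members differed from each other beyond their errors (chi-square heterogeneity that treats members as independent, p = 3.15e-31, and 6.09e-09 without the called members). Without the block the p was 0.065. Whether every member is made in that tissue alone was not tested, so this heterogeneity does not decide about a share of tissue. A scaling factor moves all genes of a comparison alike, yet the median of the list at 26 h lay at -0.164 relative to the median of all genes, which argues against scaling as the cause. The SE of 0.0221 is over members of the same libraries and does not measure the spread between pools. Of 100 swaps within the pairs that the residual correlations show, 2, the real one among them, gave a median over the times as far from 0 (highest other -0.124). Without the block, 17 of 100 splits that mix the replicate numbers did so (highest other 0.164). Few swaps within pairs thus went as far, but the pairing was found in the same libraries, so chance is not excluded. A response to rivals that differs between genes of the accessory gland is a hypothesis that rests on this pairing, found and tested on the same libraries. Chance and a different share of tissue stay open.

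The second pattern is the higher level of ribosome assembly transcripts in the abdomen with rivals at 26 and 50 h. The 49 members that had not prompted the list were still higher at 50 h (p = 0.000169 with an estimated correlation). Of 100 splits, 1, the real one, gave a median over the times as far from 0, both with the replicate block (highest other 0.108) and without it (highest other -0.101), but the list was written from genes called under the real grouping, which favours that split, so these splits do not decide about chance. A response to rivals at 26 and 50 h, chance and a different share of tissues rich in such transcripts, which was not tested, stay open.

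The third pattern is the male reproductive transcripts in head and thorax in replicate 1 without rivals at 2 h. Abdominal RNA of every tissue mixed in would bring Ebp at the same share, yet the share of Ebp was 0.012 of the median share of the seminal fluid list, which argues against it. The seminal fluid share of this library was 17.7-fold above the higher of the other libraries of its group, which argues against rivals as the source of these transcripts. Its testis share (2.05%) was only 2.06-fold above that of replicate 2 (0.995%). Replicate 3 of the group stood at 0.161%, within the 0.0289 to 0.373% of the libraries with rivals at 2 h. At 26 h the testis median was higher with rivals (log2 1.40). For testis genes the libraries of the group thus differ, and rivals stay open. Of the members measured, 49 of 55 seminal fluid and 30 of 36 testis genes lay above all other libraries of head and thorax. Accessory gland and testis tissue carried over at dissection is a candidate explanation.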

How the results depend on the processing

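The replicate block for head and thorax, the groups compared alone, the library with eye transcripts left out and all alternatives to the blocked fits were tests chosen only after the result was seen. No called gene that is named changed direction. Of 64 camera calls of lists whose medians were refitted without the block, 7 changed sign, each under 1 alternative. Those at 2 h in head and thorax were antimicrobial peptides (0.10) and oxidative phosphorylation (0.11), both without replicate 3 of no rivals. Heat shock at 26 h in head and thorax changed with upper quartile scaling (0.01). From 2 to 50 h in head and thorax, seminal fluid changed without replicate 1 at 2 h (0.00) and fat body without replicate 3 at 50 h (0.04). For the interaction of rivals with body part, testis changed without replicate number 2 (-0.01) and antimicrobial peptides without number 3 (-0.09). The medians of the other lists were not refitted, and the cause of the changes below was not tested unless stated. DESeq2 moved the counts of genes for rivals in the abdomen to 2 at 2 h, 2 at 26 h, 11 at 50 h, 22 over the times and 15 for the interaction, and in head and thorax to 13, 7, 0, 6 and 44. From 2 to 50 h it called 47 and 99 genes. Of the latter, 6 were among the 11 of edgeR. Replicate block: edgeR called 15 genes at 26 h, 17 at 50 h, 52 over the times, 1 for the interaction and 195 from 2 to 50 h in the abdomen, and 1 (Cln3) over the times and 69 from 2 to 50 h in head and thorax, where the comparisons of rivals at single times stayed at 0. Same-number libraries were not alike throughout in head and thorax (lowest residual correlation -0.261) or from 2 to 50 h in the abdomen (-0.0107), although 17 of 18 and 18 of 18 libraries lay closest to their own number. With the block the calls of the heat shock, mitochondrial and fat body lists at 50 h in head and thorax had 0.144 with an estimated correlation, and Cln3 had an edgeR adjusted p = 0.0204.

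The 2 genes called over the times in the abdomen without the block became 1 with upper quartile scaling, 1 with limma-voom, 1 without replicate 2 of rivals at 2 h, and 0 to 0 without a replicate number, and leaving out replicate 3 of rivals at 50 h gave 0 to 1 calls at 50 h. In head and thorax over the times, DESeq2 size factors gave 1 and a stricter filter 1. The 11 genes from 2 to 50 h in head and thorax became 18 with upper quartile scaling, 27 with a stricter filter, fewer genes being tested, and 0 with the groups compared alone. Leaving out a library gave 2 (replicate 2 at 50 h) to 11 (replicate 2 at 2 h), with 5 without replicate 1 or 3 at 2 h and 6 without replicate 1 at 50 h. Between body parts, 8469 genes passed without those that share reads, because fewer were tested.

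In the blocked fits of the abdomen, DESeq2 gave 47, 185 and 137 genes at 2, 26 and 50 h, 329 over the times and 190 for the interaction. A stricter filter gave 30 at 50 h and 86 over the times, and the groups compared alone 183 at 26 h and 0 at 50 h. Leaving out a library gave 0 to 69 at 2 h (69 without replicate 2 of rivals), 6 (replicate 3 of no rivals) to 11 (replicate 1 of rivals) at 26 h and 0 (replicate 2 or 3 of no rivals) to 20 (replicate 3 of rivals) at 50 h. Leaving out a replicate number gave 1 (number 3) to 10 (number 2) over the times, with 2 for number 1, and 0 (number 3) to 111 (number 1) for the interaction, with 19 for number 2. Without replicate 2 of rivals at 2 h the counts were 236 and 73. The interaction had 3 with upper quartile scaling, 3 without a filter, 4 with limma-voom and 0 without genes that share reads, which leaves out CG11911 itself.

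Camera made 132 calls of lists, which became 4 with an estimated correlation and 27 with fry. Without the body parts there were 108 calls, and with the replicate block 111, 2 with an estimated correlation and 16 with fry. Of single named genes, 2199 values stayed on their side of the threshold or within the spread, 61 passed it newly, 28 lost it and 58 moved. Of the genes named in the blocked fits 479 stayed, 20 passed newly and 184 lost it. Another pseudocount did not apply to counts. Depth limits genes near the floor of 0.027 to 0.091 CPM.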

Other observations

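The tests of Turandot levels between body parts and of antimicrobial transcripts by pool were chosen only after the result was seen. The Turandot genes, secreted stress factors, varied widely between pools, with TotA at 18.4 to 1300 CPM in the abdomen. Libraries of the abdomen and of head and thorax with the same group and replicate number are here called a pool. The labels do not state whether they came from the same males. The Turandot levels in the abdomen and in head and thorax went together over the 18 pools. For TotA Pearson's r was 0.957 and Spearman's rho 0.955, for TotM 0.958 and 0.938, for TotX 0.963 and 0.924, and for TotC 0.957 and 0.953, each with permutation p = 1e-05, the smallest that the permutations can give, and the same after Benjamini-Hochberg adjustment over the 4 genes. The permutations exchanged pools across replicate numbers. In the abdomen TotA stood at 93 CPM or less in number 3 and at 116 CPM or more in numbers 1 and 2. The p-values therefore cover differences between numbers as well as between pools. Without the 2 pools farthest from the median, r was 0.948, 0.946, 0.963 and 0.948. Within replicate numbers 1, 2 and 3, with 6 pools each, r was 0.965, 0.972 and 0.657 for TotA, 0.93, 0.974 and 0.919 for TotM, 0.971, 0.935 and 0.0519 for TotX, and 0.924, 0.995 and 0.702 for TotC, so that of TotX does not hold within number 3.

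Antimicrobial transcripts were high in single pools of replicate number 3. Over 26 members, replicate 3 without rivals at 26 h stood 7.22-fold above the next library of its group in the abdomen and 11.9-fold in head and thorax, and that without rivals at 2 h 4.19-fold and 19.6-fold. Replicate 3 with rivals at 2 h stood 7.31-fold above the next in the abdomen but 1.06-fold in head and thorax, with DptA, a diptericin, at 99.3 CPM and 1.03 CPM.

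Other splits of the libraries showed how often other groupings give as many genes. For rivals in the abdomen, 1 of 100 splits, the real one, gave as many genes over the times as the real 2 (highest other 1). These splits mix the replicate numbers, which the real grouping keeps balanced, so 2 against 1 does not decide about chance. With the block, 1 of 100 swaps within pairs, the real one, gave as many as 52 (highest other 34). That argues against chance for the paired comparison, although the pairing was found in the same libraries. For the interaction in the abdomen with the block chance is not excluded, since 15 of 100 gave at least the real 1 (highest other 89). Where the real count was 0, all splits give at least as many by definition (100 of 100), so they decide nothing. The highest other count there was 492 for the interaction in the abdomen without the block, 167 over the times and 559 for the interaction in head and thorax, and 1258 for the interaction with body part. Such splits with many genes point to structure of the samples beyond the groups. Between body parts 1 of 100 splits gave as many as the real 12860 (highest other 10419), so chance is excluded.

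The comparisons of 3 with 3 libraries allow 10 splits, and 4 with the block, too few for a share under 0.05. In the abdomen the real and highest other counts were 0 and 0 at 2, 26 and 50 h and from 2 to 50 h, where 10 of 10 splits gave as many. With the block they were 0 and 0 at 2 h (4 of 4 as many), 15 and 1 at 26 h (1 of 4) and 17 and 0 at 50 h (1 of 4). They were in head and thorax 0 and 1163 at 2 h, 0 and 0 at 26 and 50 h (10 of 10 each), and 11 and 0 from 2 to 50 h (1 of 10).

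The split with 1163 genes at 2 h in head and thorax points to a structure of the samples. It set replicates 1 and 2 without rivals and replicate 1 with rivals apart from the others, and 725 genes were higher on that side, among them 26 of 43 testis and 4 of 47 seminal fluid genes. Of these, 673 (92.8%) stood over 32 times higher in the abdomen, against 1540 of 12756 genes tested (12.1%). Testis transcripts stood at 0.373% of their abdominal level or above on that side and at 0.205% or below on the other.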
